A study of Arabidopsis thaliana with 36 samples.

How the data were processed

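The data were transcript abundances of shoots and roots of wild-type Arabidopsis thaliana seedlings. Per the labels, poly(A) messenger RNA was captured with oligo(dT) beads, copied from random primers and sequenced on an Illumina instrument. Each of the 36 libraries was placed in 1 of 12 groups by the tissue, light and bacterial treatment in its labels, with 3 libraries per group. The labels describe 5 days of growth in white light, 4 days with bacteria and 4 hours of the last light treatment. Their treatment text gives shade for every sample, including those titled white light, so the light groups rest on titles and sample characteristics.

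The values were TPM, transcript abundances as deposited by the authors in 1 table of 32833 genes. TPM divides the reads of a gene by its length and scales each library to a common total, so the columns summed to between 998011 and 999087, and the sequencing depth of a library cannot be read from them. Values had 2 decimals. The submitters' processing notes name fastp, cutadapt, HISAT2, DESeq2 and the TAIR10 genome build, with no versions. The program that computed the TPM values is not given in the sources used here. The design written before the data were examined held options for counts and for normalized values, and the latter was used because the unit was TPM. No count-based test was run, and because depth is unknown no counting intervals or detection limits are given.

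Genes were identified by the deposited identifiers, 32548 of them in the reference annotation. Symbols stood beside 10871, 22 symbols had become date numbers and were not used, and 385 identifiers shared a symbol. No library was identical to another (0 pairs), and Pearson correlations between libraries of a group on the log2 scale ran from 0.976 to 0.993. Listed at 0 in every library were 5356 genes. Because an exact 0 in such a table can be a failed estimate, a gene at 0 is described only as listed at 0.

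Differences were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 and a trend of the variance on the mean. Genes entered when at least 3 libraries of the tissue reached 1 TPM. One model with a mean per group was fitted to the 18 libraries of each tissue, and one to all 36 libraries for differences between tissues. Fold changes are on this log2(TPM + 1) scale, which understates changes at low TPM and so can enlarge interactions. Benjamini-Hochberg adjustment was applied over all genes of a comparison, and genes with an adjusted p under 0.05 are called past the threshold. The 23 comparisons were, in each tissue, shade against white light within each of the 3 bacterial treatments, each bacterium against mock in each light, the interaction of shade with each bacterium, and Root918 against P. fluorescens over both lights, followed by 3 differences between root and shoot.

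A set of 27 gene lists was fixed in advance. They covered shade avoidance, auxin response, gibberellin and brassinosteroid metabolism, expansins and xyloglucan enzymes, cytokinin response regulators, the light-induced flavonoid and HY5 pathway, photosynthesis, the circadian clock, pattern-triggered immunity, salicylic acid, jasmonate, ethylene, tryptophan and camalexin synthesis, aliphatic glucosinolate synthesis, iron deficiency, ferritins, nitrogen uptake, phosphate starvation, sulfur deficiency, abscisic acid, hypoxia, sugar starvation, heat shock, touch and wounding, the cell cycle, root hairs, and the Casparian strip and suberin. Of 423 entries, 14 could not be matched to the reference and were dropped, which left 409, and 6 genes stood on 2 lists. The photosynthesis list also served as a marker of shoot tissue in roots, and the root hair and Casparian lists as markers of root tissue in shoots. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over lists and over the 7 comparisons of 1 group with another in a tissue, and again with a correlation estimated from the data. The counts of list members past the threshold were also computed with p-values adjusted over the list alone.

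The genes named in the text follow a rule fixed at the same time. It takes 20 sentinel genes of shade, light, defence and nutrient responses, and the largest rises and falls of each comparison among genes with a symbol, a mean of at least 5 TPM and no overlap between the libraries of both groups. The number was 6 each way for shade and for bacteria in white light, and 4 each way for bacteria in shade and for Root918 against P. fluorescens. For interactions the 3 smallest adjusted p-values in each direction were taken, and for each list with at least 3 members past the threshold, up to 3 members with the smallest adjusted p.

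The computation was tested on simulated data in which 100 genes of each of 2 known sizes of change were placed in the shade mock libraries. In shoots, over 20518 genes, it recovered 85% of log2 changes of 1 and 95% of those of 2, with 7 unchanged genes called. In roots, over 20819 genes, it recovered 86% and 97%, with 12 called. No recovered sign was wrong (0 in each tissue). These rates hold for the simulated data only.

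The fits were repeated with a pseudocount of 0.1, no filter on low values, the replicate number as a block, a fit of only the compared groups, omission of each library in turn, and the estimated correlation for lists. Median-ratio scaling of the libraries, camera tests for the interactions and for Root918 against P. fluorescens, and the naming of white-light mock shoot replicate 1 and shade mock root replicate 2 as libraries that stand apart were chosen after seeing the data. Overlaps of comparisons with the same mock libraries were set beside 20 simulations of unchanged groups. Summaries and figures were made with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main results.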

Results

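Shoots and roots of Arabidopsis thaliana seedlings were compared after mock treatment or inoculation with Pseudomonas fluorescens or the bacterial isolate Root918, each in white light and in shade. Shade was a red to far-red ratio of 0.65 given for 4 hours, which mimics the light reflected by neighbouring leaves. The 12 groups of 3 libraries asked how seedlings respond to shade and to each bacterium, and whether the bacteria alter the shade response. Between 18615 and 19775 genes reached 1 TPM in shoot libraries and 19029 to 20315 in root libraries, at unknown sequencing depth. Values below are mean ± SD TPM (n = 3 libraries per group) with limma's adjusted p, and fold changes are on the log2(TPM + 1) scale. The labels do not say whether replicates came from separate plates or batches of plants, so p-values measure only the spread between these samples. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so single genes rest on limma's spread over all groups of a tissue. List counts adjusted over the list alone are given where they differ from those over all genes tested.

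**Figure D1:**
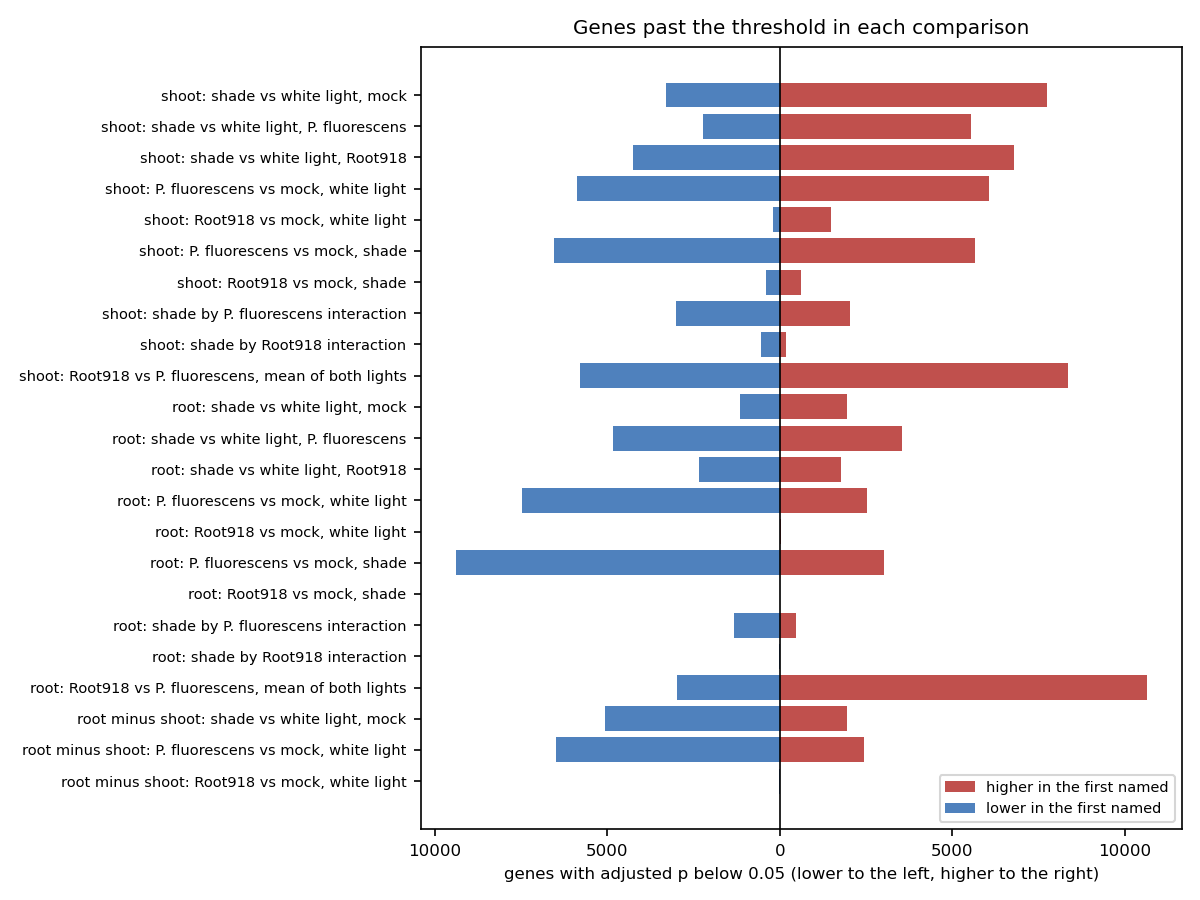
Bars show the number of genes with an adjusted p below 0.05 in each of the 23 comparisons, with genes lower in the first named group to the left and higher to the right of 0. In white light P. fluorescens changed 11961 genes in shoots and 9997 in roots, and Root918 changed 1671 and 28.

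Shade raised the early shade avoidance genes of mock shoots. PIL1 (AT2G46970), a bHLH factor induced by low red to far-red light, rose from 1.22 ± 0.721 to 41.9 ± 1.73 TPM (log2 fold change 4.32, adjusted p = 3.56e-10). HFR1 (AT1G02340), a bHLH factor that restrains the response, rose from 6.71 ± 0.769 to 193 ± 23.8 TPM (log2 fold change 4.65, adjusted p = 1.88e-11). The homeodomain factor HB-2 (AT4G16780), also known as ATHB2, rose from 8.33 ± 2.75 to 281 ± 11.6 TPM (log2 fold change 4.96, adjusted p = 1.35e-10). XTH15 (AT4G14130), a cell wall xyloglucan enzyme, rose from 7.48 ± 3 to 1029 ± 389 TPM (log2 fold change 6.89, adjusted p = 1.65e-10). The largest rise was that of ST2A (AT5G07010), a sulfotransferase of hydroxyjasmonate, from 2.43 ± 2.01 to 419 ± 37.5 TPM (log2 fold change 7.09, adjusted p = 4.25e-10), and SEN1 (AT4G35770), a gene induced by darkness and senescence, rose from 80.5 ± 46.3 to 4673 ± 398 TPM (log2 fold change 6.03, adjusted p = 3.79e-09). Among the largest falls, CYP79F1 (AT1G16410) of aliphatic glucosinolate synthesis fell from 106 ± 0.071 to 5.52 ± 1.37 TPM (log2 fold change −4.06, adjusted p = 7.46e-10). Chalcone synthase, TT4 (AT5G13930), fell from 103 ± 11.9 to 18.9 ± 4.57 TPM (log2 fold change −2.4, adjusted p = 2.91e-08).

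Of 20 measured shade avoidance genes in mock shoots, 19 rose and 1 fell, and the median of the list lay 2.43 above that of all genes (camera adjusted p = 5.22e-09, adjusted p = 0.219 with an estimated correlation). Of 30 auxin response genes 20 rose and 4 fell (camera adjusted p = 0.00056, adjusted p = 0.416 with an estimated correlation), with IAA29 (AT4G32280) rising from 3.24 ± 0.707 to 113 ± 12.9 TPM (4.75). The auxin synthesis gene YUC8 (AT4G28720) rose from 2.39 ± 1.21 to 59.9 ± 4.6 TPM (log2 fold change 4.22, adjusted p = 4.42e-09). Gibberellin and brassinosteroid metabolism had 7 of 9 genes rising, 8 when adjusted over the list alone (camera adjusted p = 0.0195, adjusted p = 0.521 with an estimated correlation). The ethylene list had 9 of 16 rising (camera adjusted p = 0.0408, adjusted p = 0.655 with an estimated correlation). All 12 touch and wounding genes rose, 11 after median-ratio scaling (camera adjusted p = 0.000704, adjusted p = 0.563 with an estimated correlation). The list is named for touch, wounding and handling, but no test tied its rise in shade to handling. Among expansins and xyloglucan enzymes 9 of 17 rose and 4 fell (camera adjusted p = 0.465), and among sugar starvation genes 6 of 10 rose and 2 fell (camera adjusted p = 0.0891).

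Of 18 light-induced flavonoid and HY5 pathway genes in mock shoots, 12 fell and 1 rose, with the list median at −1.53 relative to all genes. This call (camera adjusted p = 1.07e-09) held with an estimated correlation (adjusted p = 0.0288). Aliphatic glucosinolate synthesis fell in 10 of 11 genes (camera adjusted p = 1.51e-11, adjusted p = 0.103 with an estimated correlation). Sulfur deficiency genes fell in 7 of 11 (camera adjusted p = 4.18e-05, adjusted p = 0.417 with an estimated correlation). Cytokinin response regulators fell in 6 of 9 (camera adjusted p = 0.000378, adjusted p = 0.428 with an estimated correlation) and cell cycle genes in 9 of 15, 10 when adjusted over the list alone (camera adjusted p = 4.91e-05, adjusted p = 0.54 with an estimated correlation). Photosynthesis genes fell in 13 of 28, in 11 when adjusted over the list alone and in 18 after scaling (camera adjusted p = 1.93e-06, adjusted p = 0.618 with an estimated correlation). Jasmonate genes fell in 7 of 18 and rose in 3 (camera adjusted p = 0.011, adjusted p = 0.618 with an estimated correlation), a call lost after scaling (adjusted p = 0.0809). The clock list had 8 of 13 rising and 4 falling (camera adjusted p = 0.28). Salicylic acid genes rose in 4 of 16 and fell in 3, 3 and 3 when adjusted over the list alone, with a median and mean above 0 and a camera test pointing down (adjusted p = 0.623).

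In mock shoots 11046 of 20801 genes passed the threshold in shade, 7740 higher and 3306 lower. The median gene moved by 0.20 on the log2 scale, and after median-ratio scaling 47.6% of 10879 calls were higher in place of 70.1%. White-light mock replicate 1 stood apart from its group, with a photosynthesis list share of 14.9% of TPM against 20% and 19.6%, and with root hair and Casparian genes summing to 177 TPM against 59.2 and 63.8. In the shade mock shoots that sum was 201 to 312 TPM and the photosynthesis share 12.5% to 14.9%. The root hair list itself had 1 of 10 genes rising (camera adjusted p = 0.177), and the Casparian strip and suberin list 1 of 15 rising and 1 falling, 1 and 0 when adjusted over the list alone (camera adjusted p = 0.623).

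**Figure D2:**
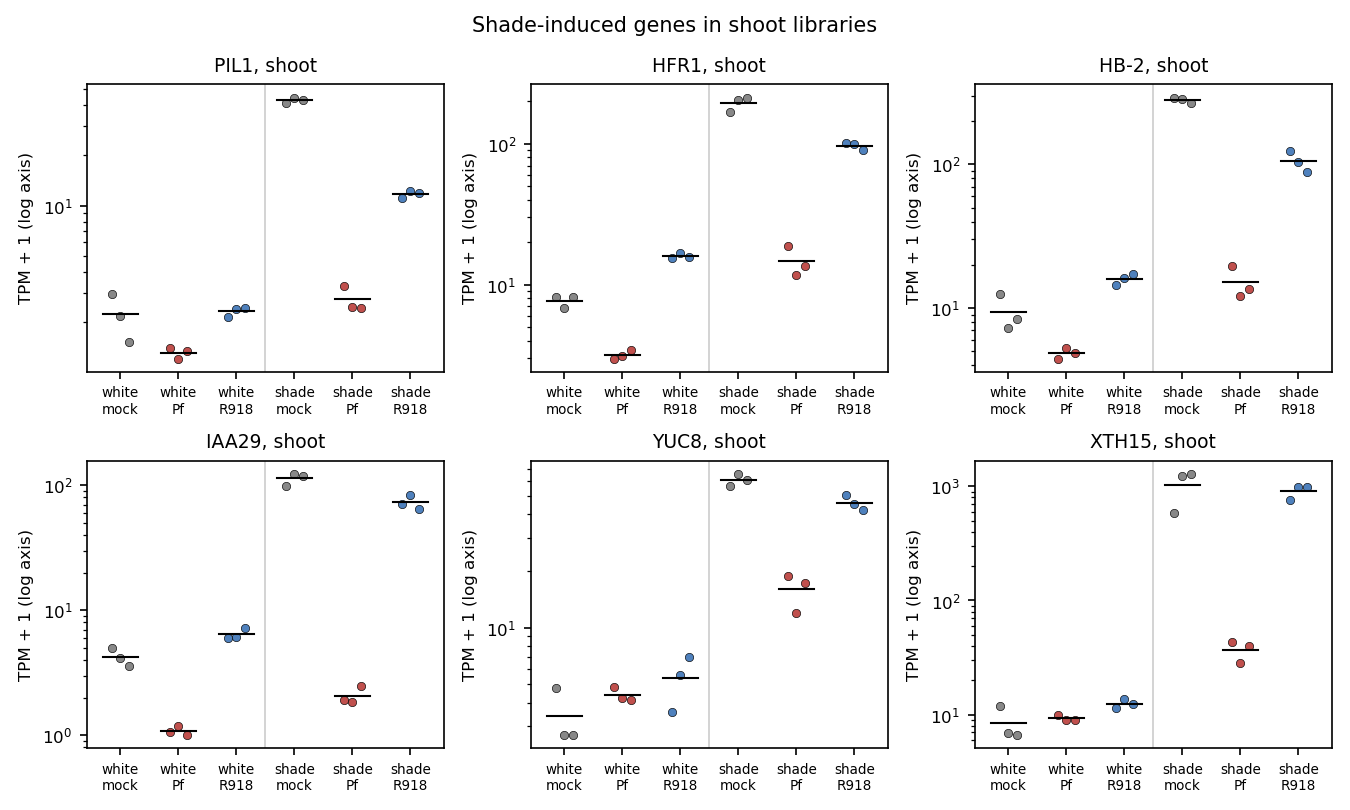
Points show single shoot libraries and bars the mean of 3 for 6 shade-induced genes, as TPM + 1 on a log axis, in white light and shade with mock, P. fluorescens (Pf) and Root918 (R918) treatment. In shade PIL1 averaged 41.9 TPM with mock, 10.8 with Root918 and 1.73 with P. fluorescens.

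With P. fluorescens the shade genes of shoots rose less. PIL1 rose from 0.307 ± 0.0971 to 1.73 ± 0.491 TPM (log2 fold change 1.05, adjusted p = 0.000567) and HFR1 from 2.18 ± 0.224 to 13.8 ± 3.69 TPM (log2 fold change 2.19, adjusted p = 8.52e-08), and XTH15 rose from 8.3 ± 0.635 to 35.9 ± 7.87 TPM (1.97). The interaction of shade with P. fluorescens was −3.27 (adjusted p = 1.22e-06) for PIL1, −2.46 (adjusted p = 1.38e-06) for HFR1, −3.34 (adjusted p = 1.39e-06) for HB-2, −3.82 (adjusted p = 5.48e-08) for IAA29 and −4.92 (adjusted p = 1.09e-06) for XTH15, over 12 libraries. In the shade avoidance list 18 of 20 members had a lower shade response with the bacterium and 1 a higher one, 19 and 1 when adjusted over the list alone (camera adjusted p = 5.57e-12, adjusted p = 0.127 with an estimated correlation). The largest rises in shade with P. fluorescens were in BRU6 (AT4G37390) from 1.94 ± 0.403 to 30.8 ± 2.67 TPM (log2 fold change 3.44, adjusted p = 3.21e-07) and GH3.3 (AT2G23170) from 63 ± 14.2 to 464 ± 67.8 TPM (log2 fold change 2.88, adjusted p = 4.9e-06), both enzymes that conjugate auxin. Auxin response genes rose in 16 of 30 and fell in 1, 17 and 1 when adjusted over the list alone (camera adjusted p = 0.0017, adjusted p = 0.472 with an estimated correlation).

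Heat shock genes of the P. fluorescens shoots fell in shade. The heat stress factor HSFA2 (AT2G26150) fell from 51 ± 16.2 to 0.663 ± 0.116 TPM (log2 fold change −4.92, adjusted p = 1.31e-08), the chaperone HSP70 (AT3G12580) fell from 427 ± 123 to 36.2 ± 2.02 TPM (log2 fold change −3.48, adjusted p = 6.81e-08) and HSP101 (AT1G74310) fell from 59.5 ± 10.1 to 4.59 ± 0.158 TPM (−3.42). Of 5 measured genes of the heat shock list, which lacks HSP70, 4 fell, 5 when adjusted over the list alone, with the list median at −3.58 relative to all genes. This call (camera adjusted p = 4.12e-08) held with an estimated correlation (adjusted p = 0.0253). So did that of the flavonoid and HY5 pathway, with 13 of 18 falling and 1 rising, 14 and 1 when adjusted over the list alone (camera adjusted p = 1.49e-10, and adjusted p = 0.0253 with an estimated correlation). All 28 photosynthesis genes fell, 27 after scaling (camera adjusted p = 3.68e-21, adjusted p = 0.283 with an estimated correlation). Abscisic acid genes fell in 8 of 16, with 9 falling and 1 rising when adjusted over the list alone (camera adjusted p = 6.23e-06, adjusted p = 0.283 with an estimated correlation), and iron deficiency genes in 5 of 15 (camera adjusted p = 0.0017, adjusted p = 0.515 with an estimated correlation). The touch list, in which all 12 genes rose in mock shoots, had 1 of 12 rising, and all 12 had a lower shade response than in mock (camera adjusted p = 2.08e-07, adjusted p = 0.306 with an estimated correlation). In total 7778 genes passed, 5555 higher and 2223 lower, with a median shift of 0.16 and 43.7% of 6422 calls higher after scaling in place of 71.4%. The interaction passed in 5038 genes, 2023 higher and 3015 lower.

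Glucosinolate genes were among those with a positive interaction of shade with P. fluorescens. FMO GS-OX3 (AT1G62560), which oxidises aliphatic glucosinolates, fell from 43.6 ± 1.57 to 3.11 ± 0.569 TPM (−3.45) in mock shoots, and its interaction was 3.23 (adjusted p = 2.95e-08) over 12 libraries. That of SOT18 (AT1G74090), a glucosinolate sulfotransferase, was 2.24 (adjusted p = 1.45e-07). Of 11 aliphatic glucosinolate genes 10 had a positive interaction (camera adjusted p = 8.57e-15, adjusted p = 0.121 with an estimated correlation), as did 6 of 11 sulfur deficiency genes, 7 when adjusted over the list alone (camera adjusted p = 1.36e-05, adjusted p = 0.322 with an estimated correlation), and 5 of 9 cytokinin response regulators, 8 when adjusted over the list alone (camera adjusted p = 4.47e-05, adjusted p = 0.306 with an estimated correlation).

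Root918 shoots also responded to shade, with lower induction of part of the shade genes. PIL1 rose from 1.32 ± 0.157 to 10.8 ± 0.614 TPM (log2 fold change 2.34, adjusted p = 7.38e-08), HFR1 from 15 ± 0.666 to 95.8 ± 5.52 TPM (log2 fold change 2.59, adjusted p = 2.2e-09) and HB-2 from 15 ± 1.46 to 105 ± 17.8 TPM (log2 fold change 2.72, adjusted p = 2.59e-08), while XTH15 rose from 11.5 ± 1.11 to 912 ± 130.2 TPM (log2 fold change 6.19, adjusted p = 4.14e-10). The interaction of shade with Root918 was −1.98 (adjusted p = 0.00169) for PIL1, −2.06 (adjusted p = 0.000218) for HFR1, −2.24 (adjusted p = 0.00109) for HB-2 and −1.25 (adjusted p = 0.00637) for IAA29, over 12 libraries. For YUC8 it was −1.08 (adjusted p = 0.0983) and for XTH15 −0.71 (adjusted p = 0.327), neither past the threshold. Of 20 shade avoidance genes 16 rose and 1 fell in shade with Root918 (camera adjusted p = 8.91e-06, adjusted p = 0.345 with an estimated correlation), and 8 had a negative interaction, 13 when adjusted over the list alone (camera adjusted p = 1.99e-09, adjusted p = 0.129 with an estimated correlation).

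Starvation and amino acid genes were among the largest rises in Root918 shoots in shade. BCAT-2 (AT1G10070), a branched-chain amino acid transaminase, rose from 1.81 ± 0.91 to 389 ± 74.6 TPM (log2 fold change 7.16, adjusted p = 2.54e-10), SEN1 rose from 107 ± 41.8 to 8209 ± 584 TPM (log2 fold change 6.32, adjusted p = 2.16e-09) and ASN1 (AT3G47340), a dark-induced asparagine synthetase, rose from 23.8 ± 12.2 to 1238 ± 62.8 TPM (log2 fold change 5.77, adjusted p = 2.15e-09). Sugar starvation genes rose in 8 of 10 (camera adjusted p = 0.000178, adjusted p = 0.345 with an estimated correlation), and 0 of 10 passed in the interaction over all genes, 7 when adjusted over the list alone (camera adjusted p = 3.43e-07, adjusted p = 0.129 with an estimated correlation). Pattern-triggered immunity genes rose in 17 of 21 and fell in 1 (camera adjusted p = 0.00125, adjusted p = 0.691 with an estimated correlation), with rises of WRKY33 (AT2G38470) from 22.1 ± 2.31 to 90.8 ± 15.9 TPM (log2 fold change 1.98, adjusted p = 0.000216) and the receptor kinase gene FRK1 (AT2G19190) from 4.55 ± 1.81 to 45.6 ± 21.9 TPM (log2 fold change 3.03, adjusted p = 0.00744). Interactions of WRKY33 (1.18, adjusted p = 0.202) and FRK1 (1.69, adjusted p = 0.469) did not pass. Photosynthesis genes fell in 27 of 28 (camera adjusted p = 4.93e-11, adjusted p = 0.507 with an estimated correlation). Flavonoid and HY5 genes fell in 14 of 18 and rose in 1 (camera adjusted p = 5.35e-07, adjusted p = 0.0886 with an estimated correlation). Aliphatic glucosinolate genes fell in 10 of 11 (camera adjusted p = 3.92e-11, adjusted p = 0.103 with an estimated correlation). Phosphate starvation genes fell in 6 of 16 (camera adjusted p = 0.0122, adjusted p = 0.802 with an estimated correlation). The suberin gene FAR1 (AT5G22500) rose from 21.7 ± 6.39 to 243 ± 8.4 TPM (3.47). It carried most of the rise in root hair and Casparian genes, which summed to 320 to 382 TPM in shade against 72.1 to 119 in white light.

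In Root918 shoots 11062 genes passed in shade, 6792 higher and 4270 lower, with a median shift of 0.10 and 50.1% of 11459 calls higher after scaling in place of 61.4%. The interaction with Root918 passed in 729 genes, 177 higher and 552 lower, and after scaling in 1079, with 57.6% higher in place of 24.3%. It passed in 2650 genes without white-light mock replicate 1, in 264 without shade Root918 replicate 3, and in 182 with only the compared groups in the fit. Shade effects in mock and Root918 shoots shared no libraries, with r = 0.793 across genes, which are not independent replicates. Higher in both were 5481 genes, against 2527 if the lists were independent, and lower in both were 2799, against 679. For mock and P. fluorescens shoots r was 0.458, with 3612 genes higher in both against 2067 and 1336 lower in both against 353.

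P. fluorescens raised jasmonate genes of shoots in white light. JAZ10 (AT5G13220), a repressor of jasmonate signalling that jasmonate induces, rose from 2.97 ± 0.786 to 205 ± 10 TPM (log2 fold change 5.71, adjusted p = 2.89e-12) and VSP2 (AT5G24770), a vegetative storage protein gene, rose from 12.2 ± 11.5 to 505 ± 89.7 TPM (log2 fold change 5.59, adjusted p = 1.36e-08). JRG21 (AT3G55970), a jasmonate-regulated oxygenase, rose from 1.77 ± 0.375 to 650.2 ± 44.6 TPM (log2 fold change 7.88, adjusted p = 1.18e-14). The ERF factor RAP2.6 (AT1G43160) had the largest rise, from 0.92 ± 0.615 to 937 ± 37.3 TPM (log2 fold change 8.98, adjusted p = 4.02e-14). All 18 measured jasmonate genes rose, with a list median of 4.63 relative to all genes (camera adjusted p = 1.3e-13, adjusted p = 0.103 with an estimated correlation). Among 16 ethylene genes 12 rose and 2 fell (camera adjusted p = 0.00277, adjusted p = 0.515 with an estimated correlation), and the defensin PDF1.2 (AT5G44420) rose from 7.44 ± 10.7 to 109 ± 18.7 TPM (log2 fold change 4.66, adjusted p = 0.000195). Pattern-triggered immunity genes rose in 15 of 21 (camera adjusted p = 0.0017, adjusted p = 0.706 with an estimated correlation), with WRKY33 rising from 25.6 ± 15.2 to 181 ± 45.4 TPM (log2 fold change 2.91, adjusted p = 3.58e-06). Tryptophan and camalexin genes rose in 13 of 16 (camera adjusted p = 0.000225, adjusted p = 0.6 with an estimated correlation), with PAD3 (AT3G26830) of camalexin synthesis rising from 3.14 ± 3.44 to 18 ± 7.01 TPM (2.44). Of 16 salicylic acid genes 1 rose and 1 fell (camera adjusted p = 0.715). The salicylic acid marker PR1 (AT2G14610) was at 26.9 ± 31.2 against 4.16 ± 7.15 TPM (log2 fold change 2.91, adjusted p = 0.0528), which passed after scaling (adjusted p = 0.0446), and FRK1 was at 10.1 ± 2.95 against 7.96 ± 13.6 TPM (log2 fold change 1.79, adjusted p = 0.0858).

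Growth and photosynthesis genes fell with P. fluorescens in the same shoots. The expansin EXPA8 (AT2G40610) fell from 102 ± 14.7 to 1.37 ± 0.478 TPM (log2 fold change −5.45, adjusted p = 4.08e-13) and the gibberellin-regulated GASA6 (AT1G74670) fell from 209 ± 29.7 to 4.04 ± 1.42 TPM (log2 fold change −5.4, adjusted p = 6.4e-12). Of 30 auxin response genes 24 fell and 2 rose, 25 and 2 when adjusted over the list alone (camera adjusted p = 1.07e-09, adjusted p = 0.109 with an estimated correlation), of 17 expansins and xyloglucan enzymes 11 fell and 4 rose, 11 and 5 when adjusted over the list alone (camera adjusted p = 0.0336, adjusted p = 0.635 with an estimated correlation), and of 15 cell cycle genes 14 fell (camera adjusted p = 5.33e-05, adjusted p = 0.54 with an estimated correlation). All 28 photosynthesis genes fell (camera adjusted p = 6.26e-09, adjusted p = 0.54 with an estimated correlation), and the list's share of TPM was 8.61% to 9.45%. In these white-light shoots, HFR1 fell from 6.71 ± 0.769 to 2.18 ± 0.224 TPM (−1.28) and PIL1 from 1.22 ± 0.721 to 0.307 ± 0.0971 TPM (−0.72). Shade avoidance genes fell in 10 of 20 and rose in 4, 12 and 4 when adjusted over the list alone (camera adjusted p = 0.062).

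Heat shock, sugar starvation and abscisic acid genes rose with P. fluorescens. HSFA2 rose from 1.22 ± 0.899 to 51 ± 16.2 TPM (log2 fold change 4.57, adjusted p = 5.79e-10) and HSP90.1 (AT5G52640) from 7.51 ± 4.34 to 153 ± 41 TPM (log2 fold change 4.26, adjusted p = 5.31e-09), and 4 of 5 heat shock genes rose and 1 fell (camera adjusted p = 0.0318, adjusted p = 0.348 with an estimated correlation). Sugar starvation genes rose in 8 of 10 (camera adjusted p = 0.000277, adjusted p = 0.348 with an estimated correlation). Abscisic acid genes rose in 10 of 16 and fell in 1 (camera adjusted p = 0.00221, adjusted p = 0.515 with an estimated correlation). Touch and wounding genes rose in 11 of 12 (camera adjusted p = 6.83e-05, adjusted p = 0.515 with an estimated correlation), which alone does not show handling. The hypoxia list had 6 of 12 rising and 1 falling (camera adjusted p = 0.158). In total 11961 genes passed, 6078 higher and 5883 lower.

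**Figure D3:**
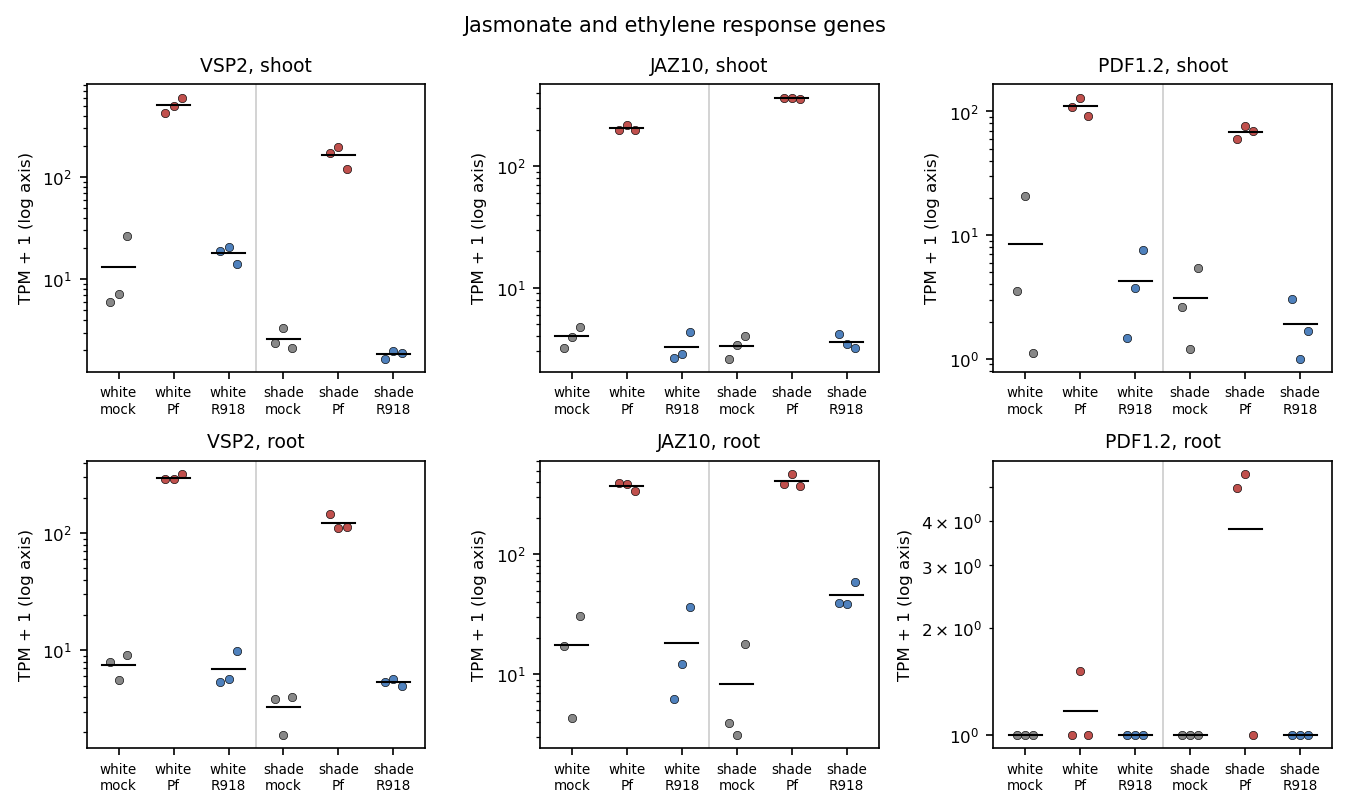
Points show single libraries and bars the mean of 3 for VSP2, JAZ10 and PDF1.2 in shoots (upper panels) and roots (lower panels), as TPM + 1 on a log axis, by light and bacterial treatment. In shoots JAZ10 averaged 205 TPM with P. fluorescens (Pf) and 2.97 TPM with mock in white light, and in roots 371 and 16.4.

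Root918 changed far fewer shoot genes in white light, and heat shock genes led by size. HSP70 rose from 19.2 ± 4.34 to 115 ± 21.7 TPM (log2 fold change 2.53, adjusted p = 4.24e-05) and HSP90.1 rose from 7.51 ± 4.34 to 29.2 ± 3.5 TPM (log2 fold change 1.94, adjusted p = 0.00151). The co-chaperone Hop3 (AT4G12400) rose from 4.52 ± 0.832 to 16.1 ± 1.9 TPM (log2 fold change 1.64, adjusted p = 0.000264). Of 5 heat shock genes 3 rose, with a list median of 1.15 relative to all genes (camera adjusted p = 0.00301, adjusted p = 0.219 with an estimated correlation). Shade genes rose modestly in white light, HFR1 from 6.71 ± 0.769 to 15 ± 0.666 TPM (log2 fold change 1.06, adjusted p = 0.000966) and HB-2 from 8.33 ± 2.75 to 15 ± 1.46 TPM (log2 fold change 0.81, adjusted p = 0.0197), and 5 of 20 shade avoidance genes rose, 8 when adjusted over the list alone and 3 after scaling (camera adjusted p = 0.0185, adjusted p = 0.635 with an estimated correlation). Flavonoid and HY5 genes fell in 7 of 18, in 9 when adjusted over the list alone, with a median of −0.44 relative to all genes. This call held with an estimated correlation (camera adjusted p = 1.31e-10, and adjusted p = 0.0253 with an estimated correlation), and TT4 fell from 103 ± 11.9 to 53.3 ± 13.9 TPM (log2 fold change −0.95, adjusted p = 0.00456). Sulfur deficiency genes fell in 3 of 11, 4 when adjusted over the list alone (camera adjusted p = 1.65e-06, adjusted p = 0.345 with an estimated correlation). Clock genes rose in 4 of 13, 5 when adjusted over the list alone (camera adjusted p = 0.0171, adjusted p = 0.428 with an estimated correlation). No jasmonate gene passed in limma (0 of 18, also over the list alone), although camera placed the list below other genes (camera adjusted p = 0.0088, adjusted p = 0.6 with an estimated correlation), and the call was lost after scaling (adjusted p = 0.169). JAZ10 was at 2.27 ± 0.919 against 2.97 ± 0.786 TPM (log2 fold change −0.3, adjusted p = 0.341), and WRKY33 at 22.1 ± 2.31 against 25.6 ± 15.2 TPM (log2 fold change −0.04, adjusted p = 0.961).

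These 1671 genes, 1474 higher and 197 lower, depended on the libraries used. The median shift was 0.12, and after scaling 46.1% of 1647 calls were higher in place of 88.2%. Without white-light mock replicate 1, the library with more root marker TPM, 6961 genes passed, without mock replicate 2 477, without mock replicate 3 589, without Root918 replicate 1 847 and without Root918 replicate 2 873, and 2 passed with only the compared groups in the fit.

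In shade P. fluorescens lowered the shade and growth genes of shoots. IAA29 had the largest fall, from 113 ± 12.9 to 1.07 ± 0.343 TPM (log2 fold change −5.79, adjusted p = 1.44e-13). PIL1 fell from 41.9 ± 1.73 to 1.73 ± 0.491 TPM (log2 fold change −3.99, adjusted p = 9.06e-11), HFR1 from 193 ± 23.8 to 13.8 ± 3.69 TPM (−3.74), HB-2 from 281 ± 11.6 to 14.1 ± 3.96 TPM (−4.25) and XTH15 from 1029 ± 389 to 35.9 ± 7.87 TPM (−4.74). Of 20 shade avoidance genes 17 fell and 1 rose (camera adjusted p = 1.98e-07, adjusted p = 0.283 with an estimated correlation). Of 30 auxin response genes 24 fell and 2 rose (camera adjusted p = 4.49e-10, adjusted p = 0.103 with an estimated correlation). All 9 gibberellin and brassinosteroid genes fell (camera adjusted p = 4.17e-05, adjusted p = 0.234 with an estimated correlation). Expansins and xyloglucan enzymes fell in 14 of 17 and rose in 1 (camera adjusted p = 8.86e-05, adjusted p = 0.348 with an estimated correlation). All 18 jasmonate genes rose (camera adjusted p = 8.57e-15, adjusted p = 0.102 with an estimated correlation), with JRG21 from 1 ± 0.501 to 1157 ± 141 TPM (log2 fold change 9.2, adjusted p = 2.35e-15) and JAZ10 from 2.31 ± 0.691 to 365 ± 3.75 TPM (6.81). Aliphatic glucosinolate genes rose in 10 of 11 and fell in 1 (camera adjusted p = 6.49e-06, adjusted p = 0.284 with an estimated correlation). Tryptophan and camalexin genes rose in 14 of 16 (camera adjusted p = 6.49e-06, adjusted p = 0.515 with an estimated correlation) and nitrogen genes in 8 of 14 (camera adjusted p = 0.0122, adjusted p = 0.54 with an estimated correlation). In total 12223 genes passed, 5673 higher and 6550 lower.

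Root918 in shade lowered part of the shade genes and raised starvation genes of shoots. PIL1 fell from 41.9 ± 1.73 to 10.8 ± 0.614 TPM (log2 fold change −1.87, adjusted p = 0.000105), HB-2 from 281 ± 11.6 to 105 ± 17.8 TPM (log2 fold change −1.42, adjusted p = 0.00166) and HFR1 from 193 ± 23.8 to 95.8 ± 5.52 TPM (log2 fold change −1.0, adjusted p = 0.00226). Of 20 shade avoidance genes 7 fell, 10 when adjusted over the list alone (camera adjusted p = 2.32e-09, adjusted p = 0.219 with an estimated correlation). DIN10 (AT5G20250), a dark-induced raffinose synthase, rose from 498 ± 61.6 to 992 ± 151 TPM (log2 fold change 0.99, adjusted p = 0.00486). MSS1 (AT5G26340), a hexose transporter, rose from 13.9 ± 3 to 45.1 ± 16 TPM (1.59), in a sugar starvation list with 6 of 10 rising, 8 when adjusted over the list alone (camera adjusted p = 8.82e-07, adjusted p = 0.219 with an estimated correlation). Pattern-triggered immunity genes rose in 4 of 21, 10 when adjusted over the list alone (camera adjusted p = 9.64e-07, adjusted p = 0.515 with an estimated correlation). Sulfur deficiency genes fell in 6 of 11, 7 when adjusted over the list alone (camera adjusted p = 2.61e-06, adjusted p = 0.345 with an estimated correlation), and photosynthesis genes in 10 of 28, 25 when adjusted over the list alone and 2 after scaling (camera adjusted p = 1.7e-16, adjusted p = 0.345 with an estimated correlation). Ferritins rose in 2 of 3, 3 when adjusted over the list alone (camera adjusted p = 0.0017, adjusted p = 0.244 with an estimated correlation). The count was 1016, 621 higher and 395 lower, and 266 to 1215 with single libraries omitted.

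Comparisons of both bacteria with the same mock libraries share chance values. In white-light shoots r across genes was 0.182 where unchanged groups simulated against shared controls gave 0.495, and the covariance was 0.0592 beside a simulated 0.0326. Higher with both were 564 genes, against 431 if the lists were independent, and lower with both 101, against 55.7. In shade r was 0.321 (simulated 0.493), the covariance 0.128 (simulated 0.0316), with 331 genes higher against 169 and 304 lower against 124. Opposite were 401 genes in white light and 154 in shade, against 474 and 303. The 3 mock libraries of a group cannot be split into parts of at least 2, and part of the excess may come from the shared controls. Pairs with no shared control differed in sign. For P. fluorescens in shade and Root918 in white light r was −0.096, with 213 genes higher in both against 402 if independent, 40 lower against 62, and 856 opposite against 518. For P. fluorescens in white light and Root918 in shade r was 0.278, with 346 higher against 182, 281 lower against 112, and 125 opposite against 291.

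Over both lights, Root918 shoots differed from P. fluorescens shoots in 14125 genes, 8345 higher and 5780 lower. JRG21 was lower with Root918, at 1.41 ± 0.198 against 903 ± 293 TPM (n = 6 libraries each, log2 fold change −8.49, adjusted p = 2.74e-17). All 18 jasmonate genes were lower with Root918 (camera adjusted p = 4.83e-15, adjusted p = 0.121 with an estimated correlation). Auxin response genes were higher in 25 of 30 and lower in 2 (camera adjusted p = 5.05e-09, adjusted p = 0.127 with an estimated correlation). Photosynthesis genes were higher in 26 of 28 (camera adjusted p = 1.72e-06, adjusted p = 0.487 with an estimated correlation). The median shift was 0.12.

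In mock roots shade lowered flavonoid genes and raised few shade genes. Chalcone synthase TT4 fell from 811 ± 118 to 152 ± 15.5 TPM (log2 fold change −2.4, adjusted p = 3.87e-06) and chalcone isomerase TT5 (AT3G55120) fell from 193 ± 37.1 to 27.7 ± 5.18 TPM (log2 fold change −2.75, adjusted p = 3.87e-06). Of 11 flavonoid and HY5 genes 9 fell and 1 rose, 10 and 1 when adjusted over the list alone (camera adjusted p = 1.71e-11, adjusted p = 0.21 with an estimated correlation). All 9 aliphatic glucosinolate genes fell (camera adjusted p = 6.24e-07, adjusted p = 0.429 with an estimated correlation). Nitrogen genes fell in 2 of 14, 5 when adjusted over the list alone (camera adjusted p = 0.00164, adjusted p = 0.429 with an estimated correlation). Clock genes rose in 8 of 13 and fell in 1 (camera adjusted p = 0.000757, adjusted p = 0.343 with an estimated correlation). The sugar exporter SWEET12 (AT5G23660) rose from 1.23 ± 0.892 to 12.8 ± 4.89 TPM (log2 fold change 2.63, adjusted p = 0.00263) and SEN1 rose from 18.3 ± 11.6 to 99 ± 38 TPM (2.51), and sugar starvation genes rose in 4 of 9, with 4 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.0453, adjusted p = 0.792 with an estimated correlation). Of 19 shade avoidance genes 2 rose (camera adjusted p = 0.798). XTH15 rose from 66.2 ± 5.44 to 101 ± 9.38 TPM (log2 fold change 0.6, adjusted p = 0.0128), while PIL1 was at 1.46 ± 0.212 against 2.12 ± 0.314 TPM (log2 fold change −0.34, adjusted p = 0.11) and HFR1 at 10.5 ± 1.21 against 7.8 ± 2.61 TPM (log2 fold change 0.43, adjusted p = 0.221). Root hair genes fell in 1 of 10, 5 when adjusted over the list alone (camera adjusted p = 0.00856, adjusted p = 0.792 with an estimated correlation). The count was 3108, 1957 higher and 1151 lower, with 49.1% of 3156 calls higher after scaling in place of 63%. Libraries of the shade mock group had the lowest correlation within a group (0.9756). The count was 1574 to 3476 with single libraries omitted, lowest without shade mock replicate 2, and 346 with only the compared groups in the fit.

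The shade response of roots differed from that of shoots for every shade sentinel past the threshold in mock shoots. The difference of the mock roots from the mock shoots in the log2 response was −4.67 (adjusted p = 3.76e-14) for PIL1, −4.66 (adjusted p = 1.14e-13) for HB-2, −4.68 (adjusted p = 1.46e-13) for IAA29 and −6.3 (adjusted p = 1.14e-13) for XTH15, over 12 libraries. For TT4, which fell in both tissues, it was −0.01 (adjusted p = 0.987). Over all genes 7017 of 22432 differed, 1951 with a higher and 5066 with a lower response in roots, and after scaling 59.9% were higher in place of 27.8%, where the median gene differed by −0.18.

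With bacteria, shade raised starvation genes of roots and lowered heat shock genes. SEN1 rose from 129 ± 39.1 to 1172 ± 30.9 TPM (log2 fold change 3.22, adjusted p = 6e-05) with P. fluorescens and from 8.24 ± 5.1 to 266 ± 53.3 TPM (log2 fold change 4.98, adjusted p = 1.37e-05) with Root918. DIN11 (AT3G49620), a dark-induced oxygenase, rose from 18.9 ± 4.37 to 190.2 ± 48.2 TPM (log2 fold change 3.26, adjusted p = 6.87e-07) and BXL1 (AT5G49360), a beta-xylosidase, rose from 10 ± 0.652 to 119 ± 20.3 TPM (log2 fold change 3.44, adjusted p = 2.03e-07) with P. fluorescens. Sugar starvation genes rose in 8 of 9 with P. fluorescens (camera adjusted p = 9.12e-06, adjusted p = 0.29 with an estimated correlation) and in 8 of 9 with Root918 (camera adjusted p = 1.85e-08, adjusted p = 0.21 with an estimated correlation). HSP70 fell from 117 ± 24.3 to 9.26 ± 0.454 TPM (log2 fold change −3.5, adjusted p = 2.03e-07) with P. fluorescens and from 156 ± 26.7 to 15 ± 2.12 TPM (log2 fold change −3.29, adjusted p = 8.43e-07) with Root918. Heat shock genes fell in 4 of 5 with P. fluorescens (camera adjusted p = 0.00321, adjusted p = 0.21 with an estimated correlation) and in 3 of 5, 4 when adjusted over the list alone, with Root918 (camera adjusted p = 0.000209, adjusted p = 0.12 with an estimated correlation). Flavonoid and HY5 genes fell in 8 of 11 and rose in 1 with each bacterium, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.00111, adjusted p = 0.515 with an estimated correlation for P. fluorescens, and camera adjusted p = 1.05e-07, adjusted p = 0.257 with an estimated correlation for Root918). Nitrogen genes fell in 8 of 14, 9 when adjusted over the list alone, with P. fluorescens (camera adjusted p = 0.00434, adjusted p = 0.515 with an estimated correlation). With Root918 they fell in 7, 8 when adjusted over the list alone (camera adjusted p = 0.000275, adjusted p = 0.343 with an estimated correlation). Photosynthesis genes, the shoot markers, rose in 6 of 28 in P. fluorescens roots, 4 when adjusted over the list alone (camera adjusted p = 0.000222, adjusted p = 0.834 with an estimated correlation), and in Root918 roots 0 of 28 passed, with a median of 1.0 relative to all genes (camera adjusted p = 0.0316, adjusted p = 0.928 with an estimated correlation), a call lost after scaling (adjusted p = 0.0623). Their share of TPM in single root libraries was between 0.014% and 0.284%. The counts were 8367 with P. fluorescens, 3541 higher and 4826 lower, and 4113 with Root918, 1777 higher and 2336 lower, or 2375 without shade Root918 replicate 2.

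The interaction of shade with P. fluorescens in roots passed in 1791 genes, 459 higher and 1332 lower, or 44.7% of 1601 higher after scaling in place of 25.6%. It was 3.26 (adjusted p = 0.000182) for DIN11 and 2.7 (adjusted p = 0.000223) for BXL1, and −1.9 (adjusted p = 4.62e-05) for HSP101 and −2.22 (adjusted p = 1.53e-05) for ALMT1 (AT1G08430), a malate channel, over 12 libraries. Sugar starvation genes had a positive interaction in 4 of 9, 5 when adjusted over the list alone (camera adjusted p = 5.84e-05, adjusted p = 0.38 with an estimated correlation), and heat shock genes a negative one in 3 of 5 (camera adjusted p = 0.00554, adjusted p = 0.209 with an estimated correlation). The shoot marker list, photosynthesis, had 0 of 28 genes past the threshold and a median of 2.76 relative to all genes (camera adjusted p = 1.56e-07, adjusted p = 0.864 with an estimated correlation). Omission of single libraries gave 931 to 1935 genes. With Root918 the interaction passed in 14 genes, 4 higher and 10 lower, with 2341 at an unadjusted p under 0.05. They included HSP70 at −2.19 (adjusted p = 0.00935), HSP90.1 at −2.0 (adjusted p = 0.0117), Hop3 at −1.24 (adjusted p = 0.00721), and MIOX2 (AT2G19800), an inositol oxygenase, at 1.97 (adjusted p = 0.0167). Heat shock genes had a negative interaction in 2 of 5, 3 when adjusted over the list alone (camera adjusted p = 0.00064, adjusted p = 0.206 with an estimated correlation). Photosynthesis genes had 0 of 28 and 1.41 (camera adjusted p = 0.000212, adjusted p = 0.949 with an estimated correlation). With single libraries omitted the count was 7 to 32, and it was 0 with only the compared groups in the fit.

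**Figure D4:**
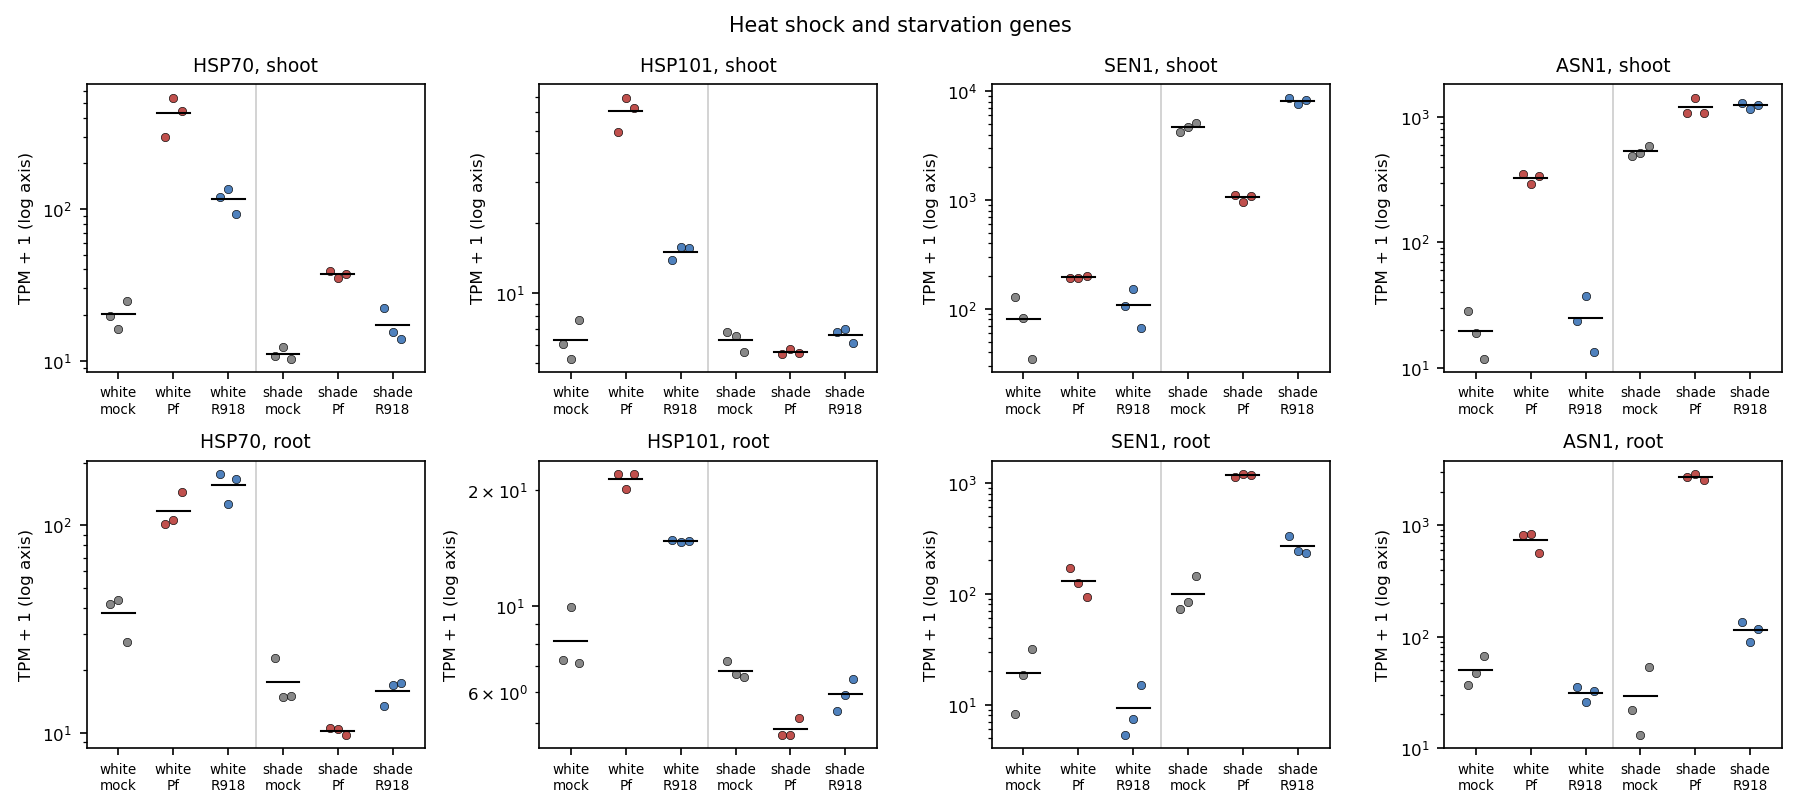
Points show single libraries and bars the mean of 3 for HSP70, HSP101, SEN1 and ASN1 in shoots (upper panels) and roots (lower panels), as TPM + 1 on a log axis, by light and bacterial treatment. HSP70 in white-light roots averaged 36.7 TPM with mock, 117 with P. fluorescens (Pf) and 156 with Root918 (R918).

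P. fluorescens raised jasmonate genes of roots in white light and lowered cell cycle and cell wall genes. JRG21 rose from 0.547 ± 0.417 to 301 ± 34.9 TPM (log2 fold change 7.64, adjusted p = 6.96e-11), VSP2 from 6.51 ± 1.79 to 298 ± 18.4 TPM (log2 fold change 5.34, adjusted p = 4.02e-09) and JAZ10 from 16.4 ± 13.2 to 371 ± 32.2 TPM (log2 fold change 4.82, adjusted p = 9.69e-05). Of 18 jasmonate genes 15 rose, with a median of 2.09 relative to all genes (camera adjusted p = 8.04e-11, adjusted p = 0.324 with an estimated correlation). Heat shock list genes rose in 3 of 5 and fell in 1 (camera adjusted p = 0.0207, adjusted p = 0.29 with an estimated correlation), a call lost after scaling (adjusted p = 0.0879). ASN1 rose from 49.5 ± 15.3 to 742 ± 152 TPM (3.9), in a sugar starvation list with 6 of 9 rising (camera adjusted p = 1.89e-05, adjusted p = 0.29 with an estimated correlation). The xyloglucan enzyme gene XTH17 (AT1G65310) had the largest fall, from 41.3 ± 15.9 to 1.22 ± 0.0551 TPM (log2 fold change −4.18, adjusted p = 9.44e-08), and expansins and xyloglucan enzymes fell in 11 of 16 and rose in 2 (camera adjusted p = 0.0207, adjusted p = 0.29 with an estimated correlation). All 15 cell cycle genes fell, 14 after scaling (camera adjusted p = 2.28e-05, adjusted p = 0.576 with an estimated correlation). Cytokinin response regulators fell in 9 of 10 (camera adjusted p = 0.00192, adjusted p = 0.394 with an estimated correlation). The iron transporter IRT1 (AT4G19690) fell from 26.7 ± 8.96 to 4.17 ± 3 TPM (log2 fold change −2.52, adjusted p = 0.00608), in an iron deficiency list with 9 of 16 falling and 2 rising, 10 and 2 when adjusted over the list alone and 6 and 2 after scaling (camera adjusted p = 0.804). The nitrate transporter NRT2:1 (AT1G08090) fell from 4.7 ± 5.84 to 0.133 ± 0.197 TPM (log2 fold change −1.83, adjusted p = 0.0114), and nitrogen genes fell in 8 of 14 (camera adjusted p = 0.174). Phosphate starvation genes fell in 8 of 16 and rose in 1, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.422), salicylic acid genes fell in 6 of 14 and rose in 1 (camera adjusted p = 0.202), and Casparian strip and suberin genes fell in 9 of 15 and rose in 1 (camera adjusted p = 0.0715). WRKY33 was at 109 ± 57.6 against 135 ± 67.7 TPM (log2 fold change −0.37, adjusted p = 0.474) and PAD3 at 10.6 ± 1.13 against 18.3 ± 6.17 TPM (log2 fold change −0.68, adjusted p = 0.0954).

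In these roots 9997 of 21101 genes passed, 2522 higher and 7475 lower. The median gene moved by −0.18, and after scaling 47.3% of 9074 calls were higher in place of 25.2%. The response to P. fluorescens in white light differed between tissues in 8914 genes, 2429 higher and 6485 lower in roots, with 53.9% higher after scaling in place of 27.2% and a median difference of −0.21. WRKY33 differed by −3.29 (adjusted p = 3.97e-05), PAD3 by −3.11 (adjusted p = 0.000104) and PDF1.2 by −4.46 (adjusted p = 0.000779), where WRKY33 and PAD3 had not passed in roots and PDF1.2 was listed at 0 in 5 of 6 root libraries. JAZ10 differed by −0.89 (adjusted p = 0.391) and VSP2 by −0.25 (adjusted p = 0.734), over 12 libraries.

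Root918 raised heat shock genes of roots in white light. HSP90.1 rose from 7.01 ± 0.917 to 32.4 ± 9.2 TPM (log2 fold change 2.02, adjusted p = 0.00026), HSP70 rose from 36.7 ± 8.85 to 156 ± 26.7 TPM (log2 fold change 2.07, adjusted p = 0.000322), Hop3 rose from 14.8 ± 0.706 to 33.3 ± 3.43 TPM (1.11) and HSP101 rose from 7.14 ± 1.61 to 13.8 ± 0.121 TPM (log2 fold change 0.88, adjusted p = 0.00427). The galactinol synthase GolS1 (AT2G47180) rose from 29.3 ± 0.681 to 53.2 ± 3.78 TPM (log2 fold change 0.84, adjusted p = 0.0441), which was lost after scaling (adjusted p = 0.0894). Of the 5 genes of the heat shock list, which lacks HSP70 and Hop3, 2 rose, 3 when adjusted over the list alone (camera adjusted p = 1e-05, adjusted p = 0.0711 with an estimated correlation). No jasmonate gene passed (limma, 0 of 18, also over the list alone), and JAZ10 was at 17.2 ± 15.9 against 16.4 ± 13.2 TPM (log2 fold change 0.09, adjusted p = 0.989). In total 28 genes passed, 27 higher and 1 lower, with 1777 at an unadjusted p under 0.05. Omission of single libraries left 12 to 18 genes, and 1 gene passed with only the compared groups in the fit. The difference of the Root918 response between tissues passed in 43 genes, 10 higher and 33 lower in roots, or 47.8% of 46 higher after scaling in place of 23.3%. Among the sentinels it passed for TT4, at 1.21 (adjusted p = 0.0374). Omission of single libraries gave 6 genes (root mock replicate 2) to 1799 (shoot mock replicate 1).

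In shade P. fluorescens moved 12417 root genes, 3019 higher and 9398 lower, with a median shift of −0.24 and 47.2% of 11726 calls higher after scaling in place of 24.3%. JRG21 rose from 0.413 ± 0.418 to 713 ± 171 TPM (log2 fold change 8.99, adjusted p = 1.03e-11), DIN11 from 0.14 ± 0.165 to 190.2 ± 48.2 TPM (log2 fold change 7.37, adjusted p = 2.34e-11) and ASN1 from 28.3 ± 20.9 to 2726 ± 174 TPM (log2 fold change 6.78, adjusted p = 2.96e-09). The nitrate transporter NRT1.5 (AT1G32450), which loads nitrate into the xylem, fell from 755 ± 279 to 25.7 ± 2.67 TPM (log2 fold change −4.77, adjusted p = 2.38e-10). Jasmonate genes rose in 17 of 18, 18 when adjusted over the list alone (camera adjusted p = 7.73e-11, adjusted p = 0.324 with an estimated correlation). Sugar starvation genes rose in 7 of 9 and fell in 1 (camera adjusted p = 1.84e-06, adjusted p = 0.257 with an estimated correlation). All 15 cell cycle genes fell, 13 after scaling (camera adjusted p = 0.000203, adjusted p = 0.687 with an estimated correlation). Iron deficiency genes fell in 12 of 16 and rose in 2 (camera adjusted p = 0.449). The shoot marker list, photosynthesis, had 0 of 28 genes past the threshold and a median of 1.4 relative to all genes (camera adjusted p = 0.00164, adjusted p = 0.855 with an estimated correlation), a call lost after scaling (adjusted p = 0.108). PAD3 fell from 17.9 ± 4.09 to 3.38 ± 1.88 TPM (log2 fold change −2.17, adjusted p = 3.82e-05), while tryptophan and camalexin genes rose in 8 of 16 and fell in 3 (camera adjusted p = 0.00918, adjusted p = 0.834 with an estimated correlation), with a median above 0, a mean of −0.131 and a call lost after scaling (adjusted p = 0.143).

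Root918 in shade changed 8 root genes, 6 higher and 2 lower, with 2880 at an unadjusted p under 0.05. They included PPDK (AT4G15530), a pyruvate phosphate dikinase, which rose from 10.7 ± 2.11 to 24.1 ± 2.9 TPM (log2 fold change 1.11, adjusted p = 0.0364). The flavonol regulator MYB12 (AT2G47460) rose from 16.8 ± 1.34 to 30.9 ± 5.36 TPM (log2 fold change 0.83, adjusted p = 0.0402). JAZ10 was at 44.6 ± 11.3 against 7.32 ± 8.3 TPM (log2 fold change 2.89, adjusted p = 0.134). No jasmonate gene passed over all genes (0 of 18 in limma), but 12 rose when adjusted over the list alone, with a list median of 1.15 relative to all genes (camera adjusted p = 5.94e-12, adjusted p = 0.29 with an estimated correlation). Sugar starvation genes behaved likewise, with 0 of 9 over all genes and 6 rising when adjusted over the list alone (camera adjusted p = 1.84e-06, adjusted p = 0.257 with an estimated correlation). The shoot marker list, photosynthesis, had 0 of 28 genes past the threshold, also over the list alone, and a median of 1.08 relative to all genes (camera adjusted p = 0.000969, adjusted p = 0.855 with an estimated correlation). Root hair genes had 0 of 10 and 0.44 (camera adjusted p = 0.00186, adjusted p = 0.687 with an estimated correlation). The count was 15 with a pseudocount of 0.1, 1 to 104 with single libraries omitted, and 0 with only the compared groups in the fit.

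In roots the responses to both bacteria had r = 0.208 in white light (simulated 0.505), with a covariance of 0.0361 beside a simulated 0.0371, 19 genes higher with both against 3.2 if independent and 1 lower against 0.40. In shade r was 0.42 (simulated 0.495) and the covariance 0.126 (simulated 0.0367), with 6 genes higher against 0.90 and 2 lower against 0.90. Here too, part of the excess may come from the shared controls. With no shared control r was 0.018 for P. fluorescens in shade and Root918 in white light, with 2 genes higher in both against 3.9 and 15 opposite against 12.2. It was 0.197 for the other pair, with 4 higher against 0.7, 2 lower against 0.7, and 0 opposite against 2.4. Shade effects in mock roots, which share no libraries with those of inoculated roots, had r = 0.447 with P. fluorescens and 0.41 with Root918 across genes. Over both lights Root918 roots differed from P. fluorescens roots in 13652 genes, 10662 higher and 2990 lower, or 54% of 12420 higher after scaling in place of 78.1%, with a median shift of 0.22. NRT1.5 was higher with Root918, at 500.1 ± 87.8 against 32.7 ± 8.12 TPM (n = 6 libraries each, log2 fold change 3.91, adjusted p = 2.35e-11), and JRG21 lower, at 1.13 ± 0.37 against 507 ± 251 TPM. Jasmonate genes were lower in 14 of 18, 15 when adjusted over the list alone (camera adjusted p = 3.3e-09, adjusted p = 0.417 with an estimated correlation). All 15 cell cycle genes were higher (camera adjusted p = 0.000195, adjusted p = 0.858 with an estimated correlation). Salicylic acid genes were higher in 13 of 14 (camera adjusted p = 0.0911, adjusted p = 0.949 with an estimated correlation, and after scaling adjusted p = 0.0144, with 12 higher and 1 lower).

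**Figure D5:**
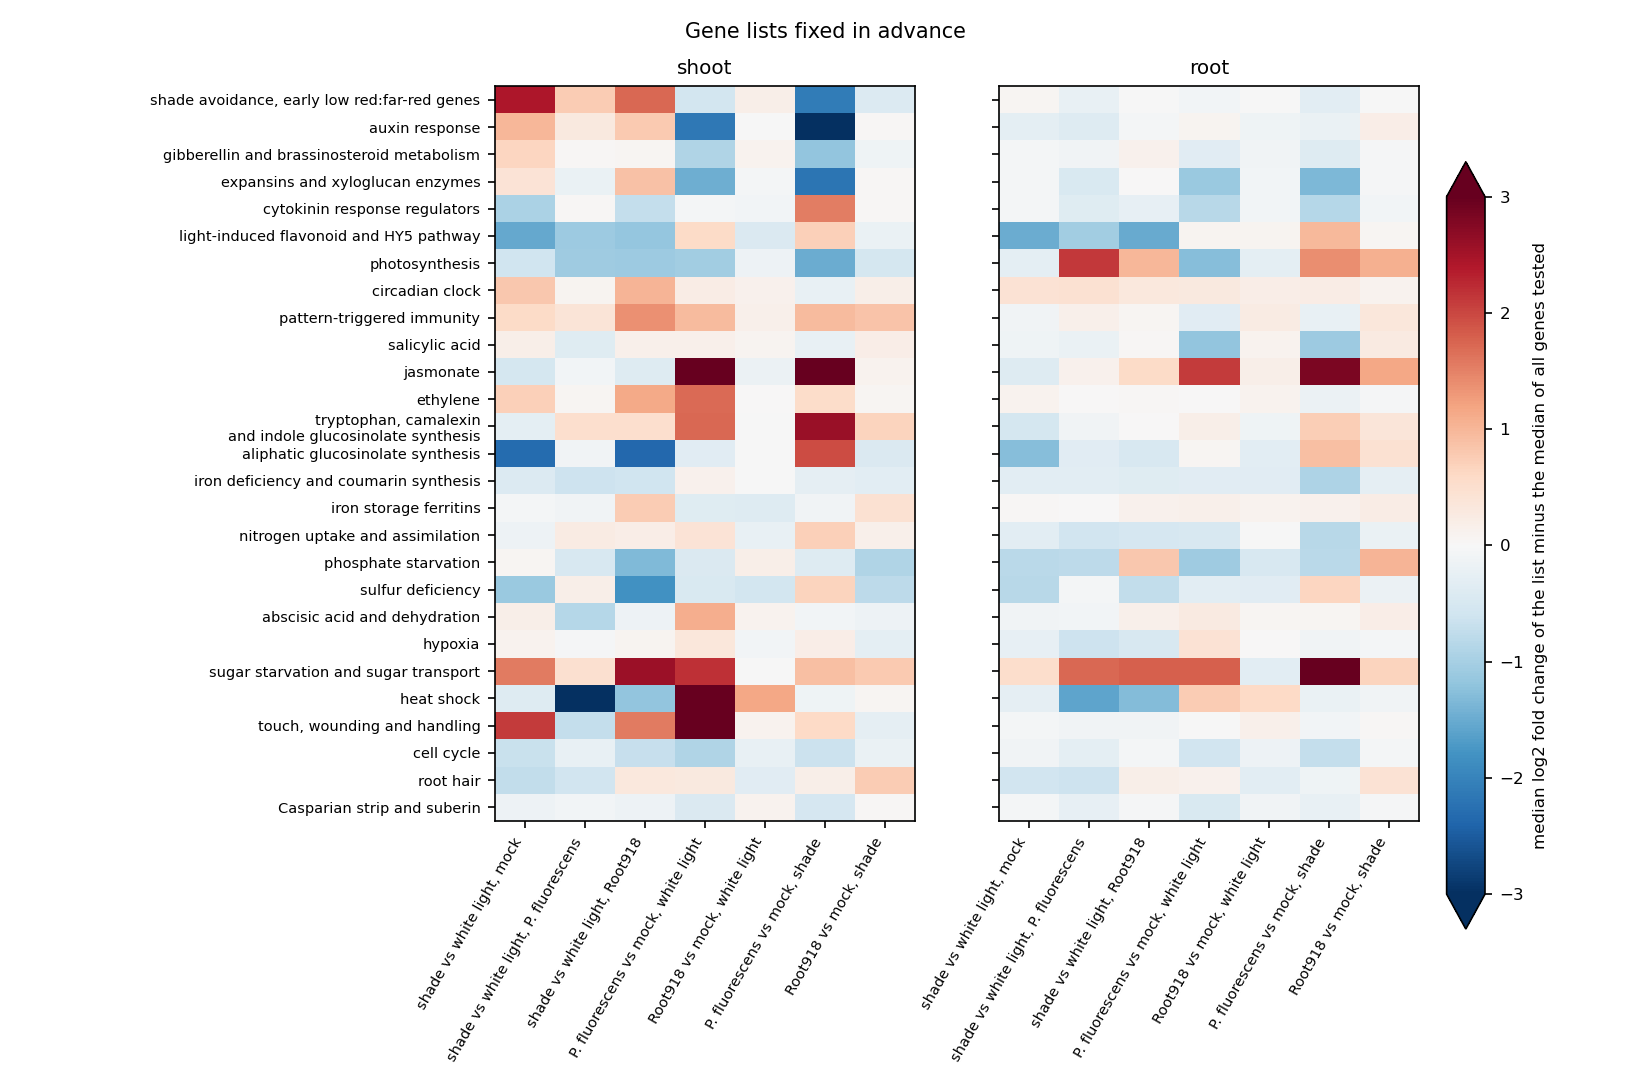
Colours show, for each of the 27 gene lists and the 7 comparisons of 1 group with another in shoots and roots, the median log2 fold change of the list minus the median of all genes tested, limited to −3 and 3. The jasmonate list with P. fluorescens in white light stood at 4.63 in shoots and 2.09 in roots, and the shade avoidance list in mock shade at 2.43 and 0.05.

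Of all camera calls at the preset correlation, 4 held with an estimated correlation. They were the flavonoid and HY5 pathway in shoots for shade with mock, shade with P. fluorescens and Root918 in white light, and heat shock in shoots for shade with P. fluorescens.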

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

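Of the tests below, those with main effects removed and most of those on the 3 patterns were chosen only after the result was seen. Differences between groups in the response to the same treatment were tested as interactions with n = 3 libraries per group.

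Shade responses of shoots differed from mock in 5038 genes with P. fluorescens and in 729 with Root918. With P. fluorescens the log2 difference was 3.23 for FMO GS-OX3, 2.54 for GSTU20 (AT1G78370), 2.24 for SOT18, 1.1 for JAZ10, −3.62 for EPR1 (AT1G18330), −3.87 for RTFL18 (AT5G16023) and −3.82 for IAA29. It was −3.27 for PIL1, −2.46 for HFR1, −3.34 for HB-2, −2.38 for YUC8, −1.85 for IAA19 and −4.92 for XTH15. With Root918 it was 1.28 for CP1 (AT5G49480), 0.99 for ASP3 (AT5G11520), 1.27 for CDPK2 (AT1G35670), −2.06 for HFR1, −1.8 for RTFL18, −1.76 for EPR1, −1.98 for PIL1, −2.24 for HB-2 and −1.25 for IAA29.

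In roots the shade response differed in 1791 genes with P. fluorescens and in 14 with Root918. With P. fluorescens the log2 difference was 3.26 for DIN11, 2.19 for MSRB6 (AT4G04840), 2.7 for BXL1, −1.43 for SKS6 (AT1G41830), −2.22 for ALMT1, −1.9 for HSP101, −0.77 for HB-2 and −1.01 for XTH15. With Root918 it was 2.71 for HSD1 (AT5G50600), 1.97 for MIOX2, −1.24 for Hop3, −2.19 for HSP70 and −2.0 for HSP90.1.

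Roots and shoots differed in 7017 genes in the response to shade, in 8914 to P. fluorescens and in 43 to Root918. Root minus shoot in shade was −4.67 for PIL1, −4.22 for HFR1, −4.66 for HB-2, −4.14 for YUC8, −2.84 for IAA19, −4.68 for IAA29, −6.3 for XTH15 and −1.8 for NRT2:1. For P. fluorescens it was 1.0 for HFR1, 1.89 for IAA19, 1.38 for IAA29, −2.83 for FRK1, −3.29 for WRKY33, −4.46 for PDF1.2, −3.11 for PAD3 and −2.2 for NRT2:1, and for Root918 1.21 for TT4.

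Every comparison was repeated on other splits of its libraries. For comparisons of 1 group with another only 10 splits exist, too few for a share under 0.05, and the real split gave the most genes in all but 1 (rank 1). In shoots the real and the highest other count were 11046 and 1608 for shade with mock, 7778 and 1 with P. fluorescens, 11062 and 1 with Root918, 11961 and 0 for P. fluorescens in white light, 12223 and 1 in shade, and 1016 and 1 for Root918 in shade. In roots they were 3108 and 3, 8367 and 2, 4113 and 2 for shade, 9997 and 0 and then 12417 and 2 for P. fluorescens in white light and shade, and 28 and 5 and then 8 and 2 for Root918. Root918 in white-light shoots was the exception, with 1671 genes against 3484 for the split that put white-light mock replicate 1 with Root918 replicates 2 and 3, so 2 of 10 were as large.

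For interactions 100 of 200 splits were drawn, and the real one is counted in. As many genes passed in 9 splits for P. fluorescens and 4 for Root918 in shoots, in 10 and 4 in roots, and in 14, 3 and 25 for the differences between tissues in shade, P. fluorescens and Root918. Such splits mix in the main effects of light and bacteria. With those effects removed the numbers were 1 and 1 in shoots, 1 and 2 in roots, and 1, 1 and 9 between tissues. The highest other counts, in that order, were 3168, 87, 15, 58, 5336, 8386 and 2302. The first splits did not exclude chance for either P. fluorescens interaction or for the tissue differences in shade and Root918. With main effects removed, a later choice, this held only for the last. There 8386 came near the real 8914, and 58 exceeded the 14 of Root918 in roots. For Root918 against P. fluorescens the number was 1 in each tissue.

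White-light mock shoot replicate 1 stood apart from its group, and the first 2 of 4 tests were written before their values were seen. Its root share was 11.4% from the root hair list and 10.9% from the Casparian list, and of 620 genes at least 2-fold higher in it 64.4% came within 2-fold once that share was added to the others, consistent with root tissue in the sample, while of 84 genes at least 2-fold lower 9.5% did. Its photosynthesis share was 14.9% against 17.6% predicted with root tissue added, and the 2 other libraries are too few to judge that gap. A shade library under that label was argued against by its PIL1 value of 1.96 TPM, and a Root918 library by its HSP70 value of 18.7 TPM. No biological explanation was tested.

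Genes of the heat shock list rose with both bacteria in white light, in P. fluorescens roots with a call lost after scaling (adjusted p = 0.0879), and all tests of this pattern were chosen after the result was seen. Handling at harvest cannot be told apart from a response to Root918, since the upper quartile of the touch list lay below the heat shock list median by more than 2 standard errors in shoots (0.54 and 1.15, standard error 0.14) but not in roots (0.31 and 0.60, standard error 0.18). The same holds for P. fluorescens, with 11 touch genes rising in shoots, and in roots an upper quartile of 0.58 against 0.77, where 2 touch genes rose and 3 fell. Heat stress that induces small heat shock genes cannot be told apart either. With P. fluorescens 3 of 4 measured small heat shock genes rose in shoots and HSP18.2 (AT5G59720) fell, with Root918 1 of 4 rose, and in roots 0 of 3 rose with either bacterium and HSP18.2 fell with P. fluorescens.

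SEN1, ASN1 and DIN10, starvation genes, rose in shade in mock shoots, although their list did not pass (camera adjusted p = 0.0891), and both tests of this pattern were chosen after the result was seen. A later harvest of the shade libraries cannot be told apart from a response to shade, because CCA1 (AT2G46830), LHY (AT1G01060), RVE8 (AT3G09600) and RVE1 (AT5G17300) all fell in mock shoots but the highest change in mock roots was 0.79. Scaling of the values was argued against, since 3 of 3 genes stayed past the threshold after median-ratio scaling.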

How the results depend on the processing

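Under median-ratio scaling, no filter, a pseudocount of 0.1 and the replicate number as a block, 1298, 1304, 1301 and 1314 results of named genes kept direction and side of the threshold. Scaling made 21 weaker and 4 stronger and reversed 1, FER1 (AT5G01600) in Root918 against P. fluorescens roots, to −0.005. With only the compared groups in the fit 88 were weaker and 9 stronger, and omission of single libraries left 9541 the same, 411 weaker and 44 stronger. Over all genes scaling reversed 47 of 13652 calls for Root918 against P. fluorescens roots, and 9696 held. It reversed 3 of 12417 for P. fluorescens in shade roots, where 9210 held, and 0 elsewhere. For lists an estimated correlation ended 220 calls, and 4 held. Scaling ended 27 list calls and gave 10, and the block ended 3, sugar starvation in mock roots in shade among them (adjusted p = 0.0543), and gave 6. TPM keeps no depth, so what depth limits is unknown. Another normalization and DESeq2, which need counts, were not run.

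With only the compared groups in the fit 2 genes passed for Root918 in white-light shoots (1671), 182 for the Root918 interaction in shoots (729), 346 for shade in mock roots (3108), 1 for Root918 in white-light roots (28), and 0 for Root918 in shade roots (8) and for the Root918 interaction in roots (14), where fewer libraries estimate the spread. Root918 in shade roots gave 15 with a pseudocount of 0.1 and 44 with the block, and the cause was not tested. Among these alternatives no other total moved by over 1.5 times. The labels do not say that replicate numbers link samples. Same-number residual correlations ran from −0.149 to 0.283 over 45 pairs in shoots and from −0.317 to 0.329 in roots, and 8 and 11 of 18 libraries correlated best with their own number.

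Without single shoot libraries, Root918 in white light gave 477 to 6961 genes: 6961 without white-light mock replicate 1, 477 and 589 without mock replicates 2 and 3, and 847 and 873 without Root918 replicates 1 and 2. Root918 in shade gave 266 to 1215, with 300 and 419 without shade mock replicates 2 and 3, and 266 and 303 without Root918 replicates 1 and 3. The Root918 interaction in shoots (729) gave 264 to 2650, with 2650 and 381 without white-light mock replicates 1 and 2, 333 without white-light Root918 replicate 1, 451 and 467 without shade mock replicates 1 and 2, and 389, 480 and 264 without shade Root918 replicates 1, 2 and 3.

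In roots, shade with mock (3108) gave 1574 to 3476, with 1678 and 1797 without white-light mock replicates 1 and 3, and 1574 and 1962 without shade mock replicates 2 and 3. Shade with Root918 (4113) gave 2375 to 4009, the lowest without shade Root918 replicate 2. Root918 in white light (28) gave 15, 18 and 16 without mock replicates 1, 2 and 3, and 12, 14 and 17 without Root918 replicates 1, 2 and 3. Root918 in shade (8) gave 1 to 104, with 2, 4 and 104 without mock replicates 1, 2 and 3, and 1 and 2 without Root918 replicates 2 and 3. The P. fluorescens interaction (1791) gave 931 to 1935, with 931 without white-light P. fluorescens replicate 3, 1097 without shade mock replicate 1, and 1141 and 1093 without shade P. fluorescens replicates 1 and 2. The Root918 interaction (14) gave 7 to 32, with 32 and 8 without white-light mock replicates 1 and 3, 7 without white-light Root918 replicate 1, and 7 and 8 without shade Root918 replicates 1 and 2. The tissue difference for Root918 (43) gave 6 to 1799, with 1799, 7 and 17 without shoot mock replicates 1, 2 and 3, 15 and 18 without shoot Root918 replicates 1 and 2, 6 without root mock replicate 2, and 16, 8 and 16 without root Root918 replicates 1, 2 and 3. The causes were not tested, apart from the root share in white-light mock shoot replicate 1.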

Other observations

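In P. fluorescens roots in shade (n = 3 libraries per group) nitrogen genes fell in 10 of 14 and rose in 1 (camera adjusted p = 0.101), and phosphate starvation genes fell in 7 of 16 and rose in 1 (camera adjusted p = 0.724). Sulfur deficiency genes rose in 6 of 11 (camera adjusted p = 0.00712, adjusted p = 0.777 with an estimated correlation), a call lost after median-ratio scaling (adjusted p = 0.0759).

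The shares of root groups below were computed only after the result was seen, and no tests were run on them. Casparian strip and suberin genes of shade mock shoots summed to 25.0%, 39.1% and 37.3% of the matching root group, while root hair genes of the same libraries reached 6.34%, 8.63% and 5.16% of it. In white-light mock shoots the Casparian shares were 17.3%, 6.79% and 7.67%, and the root hair shares 13.4%, 2.60% and 2.08%.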
